A study of Mus musculus with 2 samples.

How the data were processed

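The samples were 2 chromatin immunoprecipitation libraries against H3K4me1 from newborn mouse stomach, biological replicates 1 and 2 of 1 group, each from a pool of male and female pups (15 pups for replicate 1, number not given for replicate 2), with a library size range of 300 to 500 bp per the labels. There was no second condition, so no comparison between groups was made.

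Per the file headers and read-me texts deposited with them, the 4 files used are narrowPeak lists on mm10. Peaks of replicate 1 were called by the authors on its filtered alignment against 2 control files and peaks of replicate 2 on its filtered alignment against 1 of these, per the deposited read-me texts. A pooled list was called on both replicates together against both control files, and a list of replicated peaks was derived by the authors from the pooled list and the lists per replicate, per the same texts. The peak caller, its version, its threshold and the rule for keeping a replicated peak are not given in the sources used here. The fold enrichment of a peak over control is the authors' deposited value, a linear ratio. The significance of a peak is the authors' deposited −log10 p and −log10 q. These values were used to describe, rank or filter peaks and to compare the replicates at shared peaks. Depth and reads at the summit were also recovered from fold and p, as described below. Alignments, control files and signal tracks were not analysed here.

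The reference was GRCm38, the build named mm10 in the labels, with GENCODE M21 and its 21755 protein-coding genes on the autosomes and X, and the largest peak end on each chromosome lay within the length of that chromosome. A gene's TSS is the outermost one annotated. Peaks on unplaced contigs (1 pooled, 2 in replicate 1) were left out of location and density counts, 0 peaks lay on Y, and the first 3 Mb of each chromosome, an assembly gap, was left out of densities. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.

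The files give no read totals. Depth was recovered from the peaks: with a Poisson background, the fold and p of a peak at the genome-wide background depend only on its read number at the summit and on the background per position. The background that best joined the 2 values was 2.77 in replicate 1, 1.52 in replicate 2, whose ChIP reads had been scaled by 0.549, and 3.59 in the pooled list, whose reads had been scaled by 0.593. On that curve lay 71.2%, 67.5% and 63.0% of the peaks, and for 100% of these the fold gave a whole number of reads (within 0.02) that also returned the p (within 1e-04 on the −log10 scale). The unscaled depths of the replicates per base of smallest peak width summed to that of the pooled list (ratio 1).

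Peaks of different lists counted as shared when their overlap covered at least 50% of either. Chance was estimated with 1000 circular shifts of one list within each chromosome. Location was read from peak midpoints in the order near a TSS (1 kb), exon, intron, between genes. For the TSS profile, coverage at the TSS was set against the mean of 1 kb to either side on each of 20 chromosomes by an exact sign-flip permutation test. A promoter was CpG-rich when the 500 bp on each side of the TSS had a GC content of at least 0.5 and an observed over expected CpG ratio of at least 0.6. Gene coverage is the percent of bases within 20 kb of the TSS under a peak. The median of each of 21 gene lists (6 of stomach layers, 5 of minor cell types, 7 of other organs, and intestine, signalling and housekeeping genes) was compared with 100000 random lists of equal size, matched on the number of protein-coding TSSs in the window. All genes written for the lists were found in the annotation. Means of stomach and other-organ genes were compared by 100000 permutations of gene labels. For 16 consensus motifs, hits per kb in peaks and in flanks 5 kb away outside all peak lists gave a log2 ratio per chromosome (0.5 added to counts), from which the mean of 10 shuffled consensus sequences was subtracted, with an exact sign-flip permutation test over chromosomes. Adjusted p-values are Benjamini-Hochberg values within each family of tests, with a threshold of 0.05, and all tests are two-sided. The interval of the X to autosome ratio is an exact 95% Poisson interval of the X count. Genes, peaks and chromosomes are not biological replicates, and the p-values describe this map.

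The tests, the gene lists, the motifs, the rule for named genes and most alternatives were fixed before the data were examined. The named genes are the 3 with the highest and the 1 with the lowest coverage in each stomach list, the 2 highest of each other list, the 10 highest of the genome (at most 1 per 100 kb), the genes of the 10 largest clusters, and Hox genes that bound the range of a Hox cluster. Genes named outside this rule are said to be so. Alternatives were other overlap rules, a fold of at least 4, a −log10 q of at least 3, the pooled list, each replicate alone, other windows, distances, matching, flanks and measures. Added after the data were examined were peaks seen in both replicates, autosomes only, the mean in place of the median, the signalling list without Fgfr2, the comparison of CpG-rich with CpG-poor promoters, peaks of replicate 1 in classes of strength, and a search of gene families that share a symbol root.

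The procedures were tested on simulated data. For replicate overlap, 10% of 20 lists of 12767 randomly placed peaks were called, and 30% planted shared peaks were recovered as 31.0% against 1.72% without planting. For gene list coverage, 4.5% of 200 random lists of 15 genes and 100% of lists with 8 planted genes were called, and 2.5% of comparisons of random gene sets. For the GATA motif, sequence without signal gave a log2 difference of -0.03 (exact p = 0.177) and 0.3 planted sites per kb gave 0.30 on 19 of 19 autosomes (exact p = 3.8e-06).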

Results

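Histone H3 monomethylated at lysine 4 (H3K4me1), a mark of enhancers and of the shoulders of active promoters, was mapped by chromatin immunoprecipitation and sequencing in the stomach of newborn mice. The series held 1 group of 2 biological replicates, each a pool of stomachs from pups of both sexes, and the pool of replicate 1 came from 15 animals. The deposited peak list of replicate 1 held 102131 peaks over 30.5 Mb (1.18% of the genome), and that of replicate 2 held 12767 peaks over 3.31 Mb (0.129%). Calling on both replicates together gave 46199 peaks over 16.1 Mb, and the list of replicated peaks held 26527 peaks over 10.9 Mb (0.423%) with a median width of 348 bp. The authors' fold enrichment over control was low throughout, with a median of 3.21 in the replicated list, a range of 2.54 to 4.22 from the 5th to the 95th percentile and a maximum of 6.55. In the replicated list 74.4% of the peaks had a q-value under 0.05, against 54.5% in replicate 1 and 14 peaks in replicate 2. Background depth, recovered from the fold and p of the peaks, was 2.77 ChIP reads per position in both replicates before scaling, and the median read count at a peak summit was 11 in replicate 1 and 15 in replicate 2. Coverage values of single genes below come from 1 list each and carry no error. They are those of the replicated list unless a replicate is named, and values of the separate replicates are given for some genes only.

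The only comparison between samples that the design allows is of the 2 replicates with each other. Both carried the mark along Smad7, an inhibitor of transforming growth factor beta signalling: the region from 75347529 to 75415935 on chromosome 18 (mm10) held 37 peaks in replicate 1, 19 in replicate 2 and 18 in the replicated list. Both also marked Rara, which encodes a retinoic acid receptor (32.8% of the bases within 20 kb of its transcription start site (TSS) in replicate 1 and 12.4% in replicate 2), and Sema3f, a secreted guidance cue of axons and vessels (31.2% and 14.1%). Other loci had called peaks in replicate 1 alone, such as Ehf, an epithelial transcription factor (10.3% and 0%), and Krt15, a keratin of basal squamous cells (9.10% and 0%). Replicate 2 has far fewer peaks, and its weakest had 10 reads at the summit against 7 in replicate 1. A missing call there does not show that the mark is missing. Genome-wide, 6988 of the replicate 2 peaks (54.7%) overlapped a replicate 1 peak by at least 50% of either peak, which is 36.0 times the 1.52% ± 0.160 (SD over 1000 circular shifts of one list) found by chance position (two-sided permutation p = 0.0020, the smallest these shifts can give). The share of replicate 2 depended on the setting. It was 21.8% against only the 12767 best peaks of replicate 1, as many as replicate 2 holds, and 24.7% at a fold of at least 4 in both. Requiring 50% of both peaks gave 27.2%, and an overlap of at least 1 bp gave 67.2%. From the other side, 6766 peaks of replicate 1 (6.62%) were shared by the main rule. The shared fraction of replicate 1 was 2.31% in the weakest of 5 equal classes by p and 16.4% in the strongest, and in replicate 2 it was 47.6% in the weakest class and 65.2% in the strongest.

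Fold enrichment at shared peaks was only loosely related between the replicates, within a narrow range of values. Across the 6988 shared peaks the log2 fold enrichment had a Pearson r of 0.149 and a Spearman rho of 0.131, which describe peaks within 1 pair of libraries and not independent replicates. The median log2 difference, replicate 2 minus replicate 1, was -0.04 (SD 0.33), and 92.2% of the pairs lay within 1.5-fold. Over all peaks, fold ran from 2.39 to 4.25 in replicate 1 and from 2.71 to 4.32 in replicate 2 (5th to 95th percentile). It rests on a median of 11 and 15 reads at the summit. So narrow a range limits the correlation and makes 1.5-fold easy to meet, so neither value measures how well the strength of the mark is shared. All 26527 replicated peaks were peaks of the pooled list, of which they made up 57.4%. Of the replicated peaks 88.8% overlapped a peak of replicate 1, 35.5% a peak of replicate 2, 30.2% both and 5.88% neither. The Ehf and Krt15 peaks of the replicated list are among those without a peak of replicate 2. The 19672 pooled peaks outside the replicated list had a median fold of 2.87, and 0 of them overlapped peaks of both replicates by the 50% rule.

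The first question put to the map was where the mark lay relative to genes. Replicated peaks were concentrated in and around genes: 14864 (56.0%) had their midpoint in an intron, 1738 (6.55%) in an exon and 3470 (13.1%) within 1 kb of a protein-coding TSS, while 6455 (24.3%) lay between genes. Circularly shifted peaks gave 37.4% ± 1.05 in introns, 3.63% ± 0.201 in exons, 1.75% ± 0.128 near a TSS and 57.2% ± 1.17 between genes (mean ± SD of 1000 shifts). The mark was therefore 7.49-fold more frequent near a TSS, 1.80-fold in exons and 1.499-fold in introns than by chance position, and 0.425 times as frequent between genes. Examples are the intronic peaks of Gli2, a Hedgehog effector (chromosome 1, 119050726 to 119051455, fold 3.97), and of Srf, the serum response factor that drives muscle genes (chromosome 17, 46553303 to 46553806, fold 3.97), and an exonic peak of Sox9, a progenitor transcription factor (chromosome 11, 112784621 to 112785154, fold 4.35). The median distance of a replicated peak from the nearest TSS was 16.8 kb (quartiles 2.56 and 55.2 kb), and 75.2% of the peaks lay beyond 2.5 kb. Each of the 4 location classes had a two-sided permutation p of 0.0020 after Benjamini-Hochberg adjustment, the smallest value possible.

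Around CpG-rich TSSs the mark formed 2 shoulders with a dip between them, while CpG-poor promoters had no dip by the same measure. Of the 9741 genes with a CpG-rich promoter, 1.38% had a replicated peak over the TSS itself, 4.43% at 1 kb upstream and 10.3% at 1 kb downstream. Coverage at the TSS was lower than the mean of both sides by -5.69 ± 2.18 percentage points (mean difference ± SD over 20 chromosomes), lower on 19 of them (two-sided exact sign-flip permutation p = 3.8e-06). Of the 12014 genes with a CpG-poor promoter 2.27% were covered at the TSS, 1.02% upstream and 2.83% downstream, and the difference of 0.351 ± 0.828 points had an exact p of 0.0736. The direct comparison of the classes, chosen after seeing the data, gave -6.04 ± 2.35 points for CpG-rich minus CpG-poor promoters (exact p = 3.8e-06), -11.1 in replicate 1 alone (exact p = 1.9e-06) and -1.60 in replicate 2 alone (exact p = 3.8e-06). In replicate 1 alone CpG-rich promoters had 4.54% at the TSS and 18.6% at 1 kb downstream, and in replicate 2 alone, with 0.359% and 2.86%. For CpG-poor promoters the difference was 2.25 points in replicate 1 (exact p = 1.7e-05) and -0.0807 in replicate 2 (exact p = 0.402). Chromosomes served as blocks here and are not biological replicates.

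**Figure D1:**
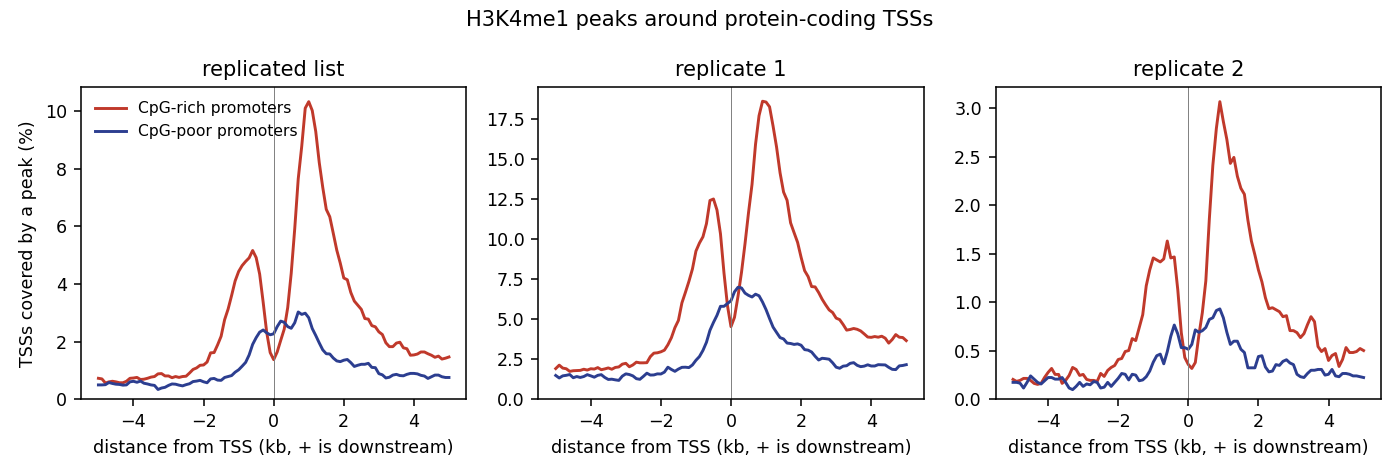
Share of protein-coding TSSs covered by an H3K4me1 peak (%, vertical axis, scaled separately per panel) against distance from the TSS (kb, positive downstream), for CpG-rich (red) and CpG-poor (blue) promoters in the replicated list, replicate 1 and replicate 2. In the replicated list the red line dips to 1.38% at the TSS and peaks at 10.3% at 1 kb downstream.

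In the replicated list Rara had the highest coverage of all 21755 protein-coding genes, 30.6% of the bases within 20 kb of its TSS. Rxra, which encodes the partner receptor of retinoic acid receptors, had 22.9%. Ski, a repressor of SMAD-dependent transcription, had 26.5% and Bcl9l, a coactivator of beta-catenin, had 24.0%. Sema3f (28.3%), the antiproliferative gene Btg2 (26.5%), Hspg2, which encodes the basement membrane proteoglycan perlecan (25.5%), the focal adhesion scaffold Bcar1 (23.9%) and the transcriptional coregulator Zmiz1 (23.1%) completed the top 10 together with G430095P16Rik (24.4%), whose strongest peak also lies in an intron of Nfix (chromosome 8, 84722502 to 84724444, fold 6.03). Rara did not lead in the other settings. Btg2 (37.5%) was above Rara (32.8%) in replicate 1 alone, and Sema3f (14.1%) was above Rara (12.4%) in replicate 2 alone. In peaks seen in both replicates Ski (24.2%) and Sema3f (21.8%) were above Rara (20.9%). Across all protein-coding genes the median in the replicated list was 0% and the mean 1.10%, and 44.5% had a replicated peak within 20 kb.

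Joining peaks less than 3 kb apart gave 17324 clusters, of which 70.99% were single peaks and 478 held 5 or more. The largest lay within Dab2ip, a Ras GTPase-activating protein, on chromosome 2 from 35668080 to 35698731, with 24 peaks and 17939 covered bases. This cluster is 125 kb from the outermost TSS of Dab2ip, and only 1.27% of the bases within 20 kb of that TSS were covered. The next were those of Zmiz1 (12496 bases), Rara (12225), Shb, a signalling adaptor (12083), Smad7 (11302) and Actn1, which encodes an alpha-actinin that crosslinks actin (10005), followed by Bcl9l (9601), Bcar1 (9578), Hspg2 (9508) and the septin gene Sept9 (9457). The Smad7 cluster ran from 75372681 to 75392535 on chromosome 18 with 16 peaks and a median fold of 4.03, and Smad7 had 22.9% coverage. No test was attached to these ranks. Which clusters were the largest depended on the list and joining rule: 5 of the 10 were also among the 10 largest in replicate 1 alone and 3 in replicate 2 alone.

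**Figure D2:**
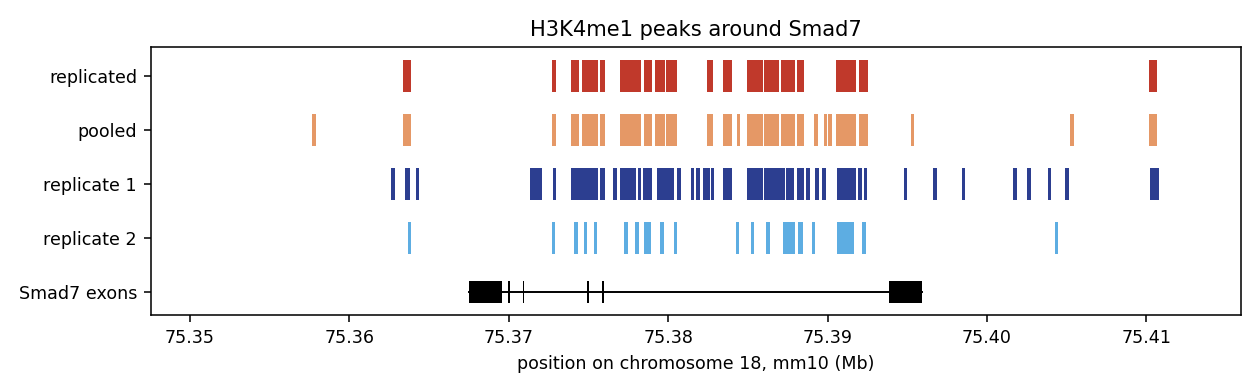
Peaks of the 4 lists (coloured boxes, one track per list) and Smad7 exons (black) along chromosome 18 in mm10 (Mb). The region holds 18 replicated, 25 pooled, 37 replicate 1 and 19 replicate 2 peaks, most of them inside the gene.

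Gene lists written before the data were examined were used to ask which cell layers and pathways of the stomach carried the mark. Of 21 lists, 3 had an unadjusted p under 0.05 and 1 lay above random lists after adjustment: genes of Hedgehog, Wnt, BMP and FGF signalling, of which 25 of 32 had a replicated peak within 20 kb of the TSS. Their median coverage was 1.02%, against a median of 0% in 100000 random lists matched on TSS density (95% of them between 0 and 0.587%, two-sided permutation p = 0.00082, adjusted p = 0.0172). Smad7 (22.9%) led the list. Its 6 members above the 95th percentile of matched genes also included Fgfr2 (10.7%) and, named after their values were seen, the BMP target genes Id3 (6.06%) and Id1 (5.78%), the secreted Wnt antagonist Sfrp1 (4.88%) and the Hedgehog receptor Ptch1 (4.64%). Shh, a Hedgehog ligand made by the epithelium, had 1.57%, and Bmp4 and Fgf10, ligands made by the mesenchyme, had 0% (also named after their values were seen). The list was also above random lists in replicate 1 alone (4.18%, adjusted permutation p = 0.00042) and in replicate 2 alone (0.231%, adjusted permutation p = 0.0193). The call was lost in 7 of 16 alternatives. Among them were the list without Fgfr2 (0.885%, adjusted permutation p = 0.0575) and random lists also matched on promoter CpG content (adjusted permutation p = 0.225). The outermost annotated TSS of Fgfr2, at 133123350 on chromosome 7, lies inside Ctbp2, and the annotated gene reaches from there to 130162451. The 10.7% was measured around that TSS and says nothing about the rest of Fgfr2.

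The layers of the stomach wall themselves did not stand above matched genes in the replicated list. Among transcription factors of the gastric endoderm 9 of 23 had a peak, led by Ehf (5.52%), the forkhead factor Foxa3 (3.37%) and Sox9 (1.33%), while Foxa1, a pioneer factor of endoderm, had 0%. Among products of the gastric epithelium 9 of 22 had a peak, led by the pepsinogen gene Pga5 (4.54%), Psca, a surface antigen of gastric epithelium (2.46%), and the chloride transporter Slc26a9 (1.87%), with Anxa10 at 0%. The strongest peaks counted for Foxa3, Pga5 and Psca lie inside the neighbouring genes Irf2bp1, Vps37c and Jrk. The forestomach, which is lined by squamous epithelium, was represented by 7 of 16 genes with a peak, led by Krt15 (2.29%), Irf6 (1.16%) and Pax9 (1.03%), with the desmosomal cadherin Dsc3 at 0%. All 3 lists had a median of 0% and none passed the permutation test (adjusted p = 1). A median of 0% means only that more members lacked a peak than had one, and the coverage of the marked members does not enter it. The same limit holds for every list below with a median of 0%. With the mean in place of the median, a choice made after seeing the data, none of these 3 lists passed either.

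General epithelial genes had a median of 0.632%, with 11 of 15 marked, led by the protease inhibitor Spint2 (3.85%), the vesicle-traffic GTPase Rab25 (3.62%) and the tight-junction gene Cldn4 (3.23%, strongest peak on chromosome 5 from 134947112 to 134947786), and with Cldn3 at 0%. Transcription factors of the gastric mesenchyme had a median of 0% with 7 of 20 marked: the Hedgehog effectors Gli2 (3.15%) and Gli1 (2.90%) and the nuclear receptor gene Nr2f2 (1.92%) led, and Barx1, a homeobox factor of stomach mesenchyme, had 0%. Smooth muscle genes had a median of 0.615% with 10 of 18 marked, led by smoothelin (Smtn, 5.93%), Srf (3.03%) and transgelin (Tagln, 3.005%, its strongest peak inside Sidt2), with the smooth muscle actin gene Acta2 at 0%. The strongest peaks counted for Rab25 and Gli1 lie inside Mex3a and Arhgap9. These 3 lists did not pass the permutation test either (adjusted p = 1).

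In replicate 1 alone, 2 of the 6 stomach lists did lie above random lists. All 15 general epithelial genes had a peak there, with a median of 5.72% against 1.41% in matched lists (adjusted permutation p = 0.00483), and Rab25 (10.9%), Spint2 (10.2%) and Cldn4 (5.46%) were well covered. All 18 smooth muscle genes had a peak, with a median of 3.64% against 1.23% (adjusted permutation p = 0.0381). Gastric mesenchyme factors (19 of 20 genes, 2.93%, adjusted permutation p = 0.0601) and endoderm factors (20 of 23, 2.54%, adjusted p = 0.108) did not pass. Barx1 had 3.72% and Foxa1 2.37% in that replicate. With the mean of a list in place of its median, a choice made after seeing the data, neither list passed in replicate 1 (general epithelium 5.59%, adjusted permutation p = 0.0598, and smooth muscle 4.04%, adjusted p = 0.146).

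Less abundant cell types of the organ wall, intestinal genes and housekeeping genes gave no call in the replicated list. Phox2a, a transcription factor of autonomic neurons (4.29%), and Gfra1, a receptor of enteric progenitors (2.48%), led enteric neurons and glia, with 6 of 18 genes marked. Insm1 (4.15%) and Isl1 (1.15%), factors of endocrine differentiation, led enteroendocrine cells (5 of 15), Eng (3.88%) and Sox18 (1.37%) led endothelium (7 of 15), and Fcer1g (4.43%) and Cd68 (3.79%) led blood and immune cells (7 of 16). The strongest peaks counted for Eng, Fcer1g and Cd68 lie inside Ak1, Ndufs2 and Tnfsf13. Of 6 genes of the interstitial cells of Cajal, the pacemaker cells of the gut, only Ano1 was marked (1.80%), and its coverage in replicate 1 was 15.0%. Etv1 had 0%. Intestinal genes were marked at 3 of 15, led by Apoa4 (1.37%) and Vil1 (0.952%). Housekeeping genes had a median of 1.21% with 9 of 16 marked, led by Actb (12.4%) and Ppia (5.40%), and their permutation p of 0.0405 did not survive adjustment (0.284), although they passed in replicate 2 alone (0.562%, adjusted permutation p = 0.0458).

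**Figure D3:**
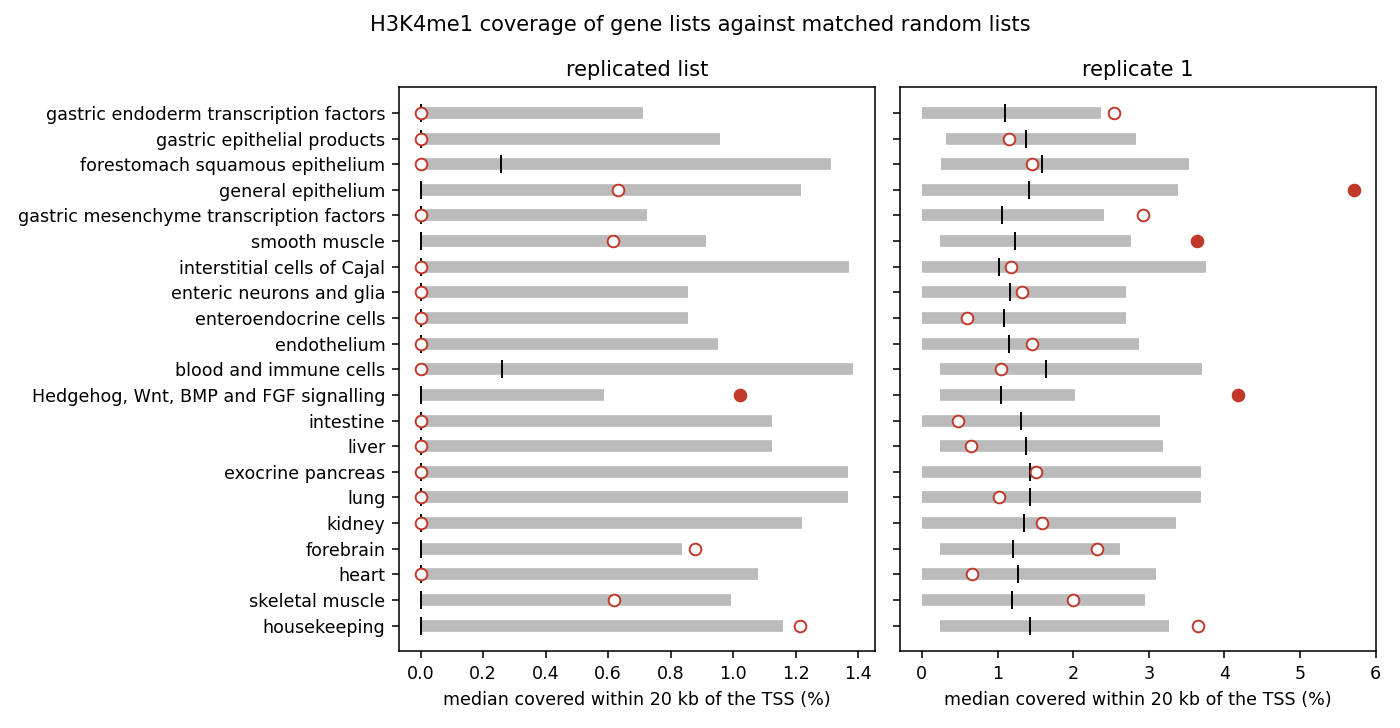
Median percent of bases within 20 kb of the TSS covered by H3K4me1 peaks (horizontal axis) for 21 gene lists in the replicated list and in replicate 1. Circles are lists, filled where the adjusted p is under 0.05, grey bars span 95% of matched random lists and black ticks their median; signalling genes reach 1.02% in the replicated list and general epithelium 5.72% in replicate 1.

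The tissue named by the labels was compared with other organs by setting the 113 genes of the 6 stomach lists against 101 genes of liver, pancreas, lung, kidney, forebrain, heart and skeletal muscle. Stomach genes were not covered more than genes of other organs: 0.810% ± 1.25 (SD over genes) of the bases were under a peak in the first set and 0.948% ± 1.95 in the second, a difference of -0.138 points that was not distinguishable from 0 (two-sided permutation p = 0.542). Several of the highest values among the other organs come from a few loci: Tnnt3 (11.5%) and Tnni2 (8.44%), troponins of fast skeletal muscle, and Scgb1a1, the lung secretoglobin (11.1%), whose strongest peak lies between genes 18.99 kb upstream of the TSS. Forebrain genes, led by the glutamate transporter gene Slc17a7 (5.75%) and Neurod2 (3.05%), had a median of 0.879% with 13 of 20 marked (permutation p = 0.0401, adjusted p = 0.284). Skeletal muscle (8 of 15 marked, median 0.620%), heart (5 of 15, led by Myl7 at 2.66% and Tnnt2 at 2.15%), liver (5 of 16, led by Apoa2 at 2.33% and Apoa1 at 1.37%), pancreas (3 of 12, Rbpjl 1.48% and Cpa2 1.26%), kidney (5 of 12, Lrp2 1.55% and Aqp2 0.917%) and lung (5 of 12, Sftpc 2.65%) did not pass. The strongest peaks counted for Myl7, Tnnt2, Apoa2, Apoa1 and Sftpc lie inside Gck, Lad1, Tomm40l, Apoa4 and Bmp1. In replicate 1 alone the order turned, with 3.36% ± 2.84 for stomach genes and 2.62% ± 3.39 for other organs, a difference of 0.738 points (permutation p = 0.0826), so neither peak list separated the tissues.

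Sequence motifs were counted in replicated peaks and in flanking sequence 5 kb away to see which binding sites the marked regions held beyond their base composition. The E-box CAGCTG, bound by basic helix-loop-helix factors, was present at 0.909 per kb in peaks and 0.544 in flanks, a log2 ratio 0.43 ± 0.14 above that of its shuffles (SD over 20 chromosomes), higher on 20 of 20 (exact sign-flip permutation, adjusted p = 3.1e-05). TEAD sites, through which the Hippo pathway acts, had 0.177 per kb against 0.139 and a log2 difference of 0.38 ± 0.47 (higher on 19, adjusted exact p = 0.00711). Chromosome X, with only 5 replicated peaks, is 1 of the 20 equally weighted chromosomes. On autosomes alone the difference was 0.47 ± 0.21 for TEAD and 0.62 ± 0.18 for the FOX motif described below. The CArG box of SRF, which drives muscle genes, was higher by 0.28 ± 0.37 (16 chromosomes, adjusted exact p = 0.00731), and AP-1 sites by 0.17 ± 0.27 (17 chromosomes, adjusted exact p = 0.0292), with 0.34 in replicate 1 alone and 0.27 in replicate 2 alone. FOX and GATA sites, bound by endoderm and mesoderm factors, were rarer in peaks than in flanks (FOX 0.243 against 0.267 per kb, though 0.263 against 0.260 in peaks beyond 2.5 kb of a TSS, GATA 0.699 against 0.970), yet less so than their shuffles, which left differences of 0.55 ± 0.35 (19 chromosomes, adjusted exact p = 0.000153) and 0.13 ± 0.11 (18 chromosomes, adjusted exact p = 0.000397). The CTCF motif, which marks insulators, had a log2 difference of -1.22 ± 0.82 (higher on 1 chromosome, adjusted exact p = 0.000122). It had 67 hits in peaks and 158 in flanks (0.00616 and 0.00928 per kb). The motif itself had a mean log2 ratio of -0.37 and its shuffles 0.85, so much of the difference came from the shuffles. Ambiguous letters let shuffles match CpGs, which the CTCF consensus cannot, and peaks were richer in CpG. A depletion beyond base composition is therefore not settled. For CTCF the difference was -1.28 in replicate 2 alone and -0.71 in replicate 1 alone, where hits were about as frequent in peaks as in flanks (0.00775 and 0.00770 per kb) and rarer only relative to the shuffles.

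The other 9 of the 16 motifs (SOX, HNF4, HNF1, KLF, ETS, NFI, MEIS, NKX and GRHL) did not pass, and HNF1 (7 hits), NFI (22 hits) and GRHL (40 hits) were too rare in peaks for a firm statement. Peaks were richer in G and C than their flanks, 52.2% against 46.3% (difference 5.88 ± 0.558 points over 20 chromosomes, exact p = 1.9e-06), and held 18.1 CpG dinucleotides per kb against 12.2. The difference for the SRF CArG box was 0.16 in replicate 1 alone, and its call was lost in replicate 2 alone (0.05, adjusted exact p = 0.963), in the pooled list (0.17, adjusted exact p = 0.217) and in the peaks seen in both replicates, where the difference was larger but on fewer peaks (0.39 ± 0.87, adjusted exact p = 0.155).

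**Figure D4:**
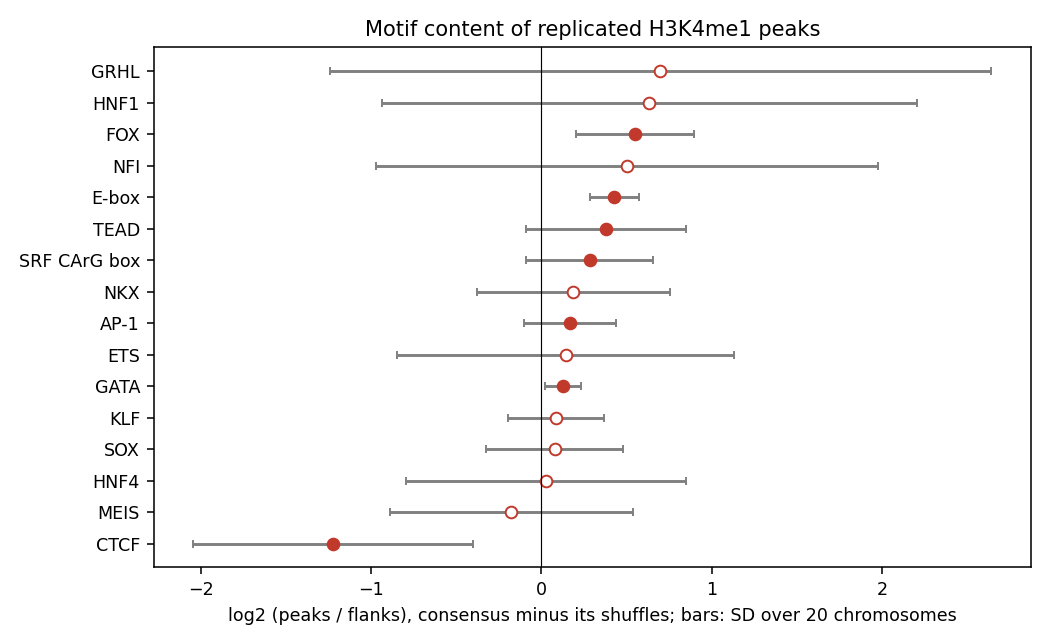
Mean log2 ratio of motif density in replicated peaks over flanks minus that of shuffled motifs (horizontal axis) for 16 motifs, with bars giving the SD over 20 chromosomes and filled circles an adjusted p under 0.05. E-box (0.43) and FOX (0.55) stand clear of 0, and CTCF (-1.22) lies below it.

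Every autosome was marked, and chromosome X held almost no peaks. Chromosome 11, which carries the Hoxb genes, Rara and Sox9, was the most densely marked (20.0 replicated peaks per Mb) and chromosome 3 the least dense autosome (6.84). Chromosome X held 5 replicated peaks, 0.0298 per Mb against 11.02 on the autosomes (SD 3.29 over 19 autosomes), a ratio of 0.00270 with an exact 95% Poisson interval of 0.000876 to 0.00630. The list of replicate 1 held 316 X peaks (1.88 per Mb against 42.3, a 22.5-fold lower density) and replicate 2 held 2. Per protein-coding gene the replicated list was 242-fold sparser on X. Intervals cover counting error only. Of the gene lists used above none held more than 2 genes on X.

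**Figure D5:**
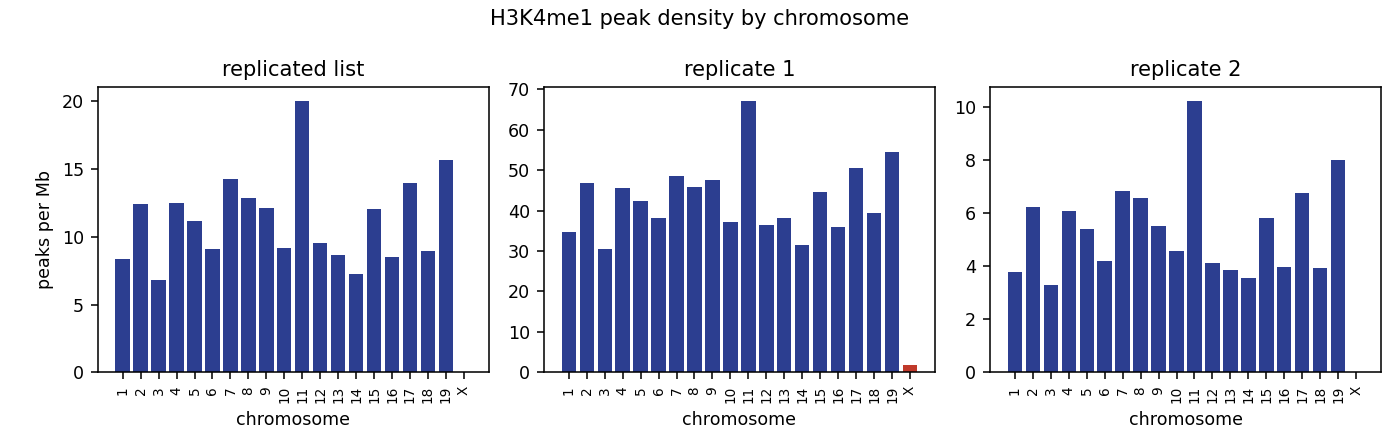
H3K4me1 peaks per Mb (vertical axis, from 0, scaled separately per panel) on each chromosome in the replicated list, replicate 1 and replicate 2. In the replicated list chromosome 11 has 20.0 peaks per Mb, and chromosome X (red, 0.0298) is too low to see.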

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

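Of 558 alternatives to the reported values (single genes apart), 483 kept the direction and the side of the threshold or, without a test, moved less than a set limit. Most of these 483 belong to gene lists that did not pass in the main setting and stayed so, which says little about robustness. Of the others 14 fell below the threshold, 16 passed it, 24 turned direction and 21 moved further. Where no reason is given the cause was not tested. The comparison of CpG-rich with CpG-poor TSSs and settings limited to peaks seen in both replicates, to autosomes, to the signalling list without Fgfr2 and to means were chosen after seeing the data. The excess of shared peaks over shifted lists, the 4 location classes, the dip at CpG-rich TSSs, its difference from CpG-poor TSSs and the E-box, FOX and TEAD motifs kept their call in all alternatives run. The planned overlap of replicates at a −log10 q of at least 3 gave no value, since 0 peaks of replicate 2 reach it. In replicate 2, 14 peaks have a q-value under 0.05.

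An overlap of at least 1 bp raised the replicated peaks seen in both replicates to 31.1%. At CpG-poor promoters the TSS difference was 0.917 in the pooled list, -0.0173 at a −log10 q of at least 3, -0.0180 at a fold of at least 4 and -0.0807 to 2.25 in the single replicates. Of the 10 largest clusters 3 were shared at a joining distance of 1 kb, 5 at the longest joining distance tried, 6 in the pooled list and 3 to 5 in the single replicates. The X to autosome ratio was 0.00527 in the pooled list and 0.00224 to 0.0444 in the single replicates.

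Signalling genes had a median of 0 at a −log10 q of at least 3, at a fold of at least 4 and in peaks seen in both replicates, where most genes have no peak left. Their median of 1.02% did not pass without matching or with matching on promoter CpG content, and neither did the median of 1 peak per window nor 0.885% without Fgfr2. Smooth muscle passed with a 100 kb window (1.61%) and had 0.231% to 3.64% in the single replicates, forebrain passed with a 5 kb window (2.98%), general epithelium had 0% to 5.72% and housekeeping genes 0.562% (passed in replicate 2) to 3.65% in the single replicates. The lists past the threshold numbered 2 with a window of 5 kb, 2 with 100 kb, 2 to 3 in the single replicates and 0 at the −log10 q minimum, at the fold minimum, in peaks seen in both replicates, without matching, with CpG matching, by peak number and without Fgfr2. At an unadjusted p under 0.05 by the permutation test these last 7 settings gave 0, 0, 0, 2, 1, 1 and 3 lists.

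Stomach genes were above those of other organs by 0.00795 points at the −log10 q minimum and 0.00297 at the fold minimum, and the difference was -0.0657 to 0.738 in the single replicates.

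Among motifs, 13 passed in replicate 1, 6 in replicate 2 and 4 at the −log10 q minimum. The 4 include HNF1 (0.13), which has 0 hits in peaks and 0 in flanks there, so its pass comes from the count added to each and from the shuffles and says nothing about HNF1; it is also among the 16 alternatives that passed the threshold. At that minimum, with 1510 peaks left, GATA (0.0855), AP-1 (0.0558), the SRF CArG box (0.24) and CTCF (-0.69) no longer passed, FOX was more frequent in peaks than in flanks (0.229 and 0.213 per kb), and SOX (-0.14), HNF4 (-0.28), KLF (-0.25) and MEIS (0.0133) turned. The SRF CArG box also failed in the pooled list (0.17), in peaks seen in both replicates (0.39) and in 1 of the single replicates (0.0545 to 0.158). SOX turned beyond 2.5 kb of a TSS (-0.0168), in peaks seen in both replicates (-0.0482) and on autosomes only (-0.00103). KLF (-0.0362) and MEIS (0.0306) turned with flanks at 20 kb, where NKX passed (0.28), and NKX turned in peaks seen in both replicates (-0.25). ETS turned in the pooled list (-0.0757) and beyond 2.5 kb (-0.00488), where NFI passed (0.69). In the single replicates AP-1 ranged from 0.27 to 0.34 and CTCF from -1.28 to -0.71, and SOX ranged from -0.0889 to 0.12, HNF4 from 0.33 to 0.77, HNF1 from -0.0292 (0 hits in peaks of replicate 2) to 1.01, KLF from -0.0236 to 0.18, NFI from -0.0948 to 0.90, MEIS from -0.0635 to 0.0437, NKX from -0.39 to 0.26 and GRHL from 0.0165 to 0.58.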

Other observations

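The tests of gene families, of gene number on X, of X peaks at other read minimums, of ChIP depth, of stomach genes in replicate 2 and of peak classes by strength were chosen after the results they concern were seen. The Hox clusters, which pattern the gut along its length, held 2 to 6 replicated peaks each and were not compared with one another by a test. From 20 kb before the first to 20 kb past the last TSS of each cluster, 1.04% of the bases were covered in HoxA, 1.03% in HoxB, 0.378% in HoxC and 0.353% in HoxD, against 0.423% of the genome. The medians of the Hoxa and Hoxb genes were not distinguishable from matched random lists (permutation p = 0.388 and 0.937). The Hoxa median was 0%, the lowest value possible, against 1.02% in random lists, so the test could not have called a depletion there. Windows of neighbouring Hox genes also overlap, and 1 gene per 100 kb leaves 2 genes each in HoxA and HoxB. The HoxB region held 6 replicated peaks, with coverage per gene from 0% at Hoxb13 to 4.5999% at Hoxb2, and Hoxb3 (4.34%) and Hoxb4 (1.86%), named after their values were seen, came next. In HoxA, 4 peaks gave a range from 0% at Hoxa3 to 2.82% at Hoxa4, and each gene from Hoxa6 to Hoxa13 had 0%. These last genes did have peaks nearby in replicate 1 alone, from 1.02% at Hoxa9 to 3.60% at Hoxa6, and had 0% in replicate 2 alone. HoxC held 2 peaks (0% at Hoxc13, 0.702% at Hoxc4) and HoxD 2 (0% at Hoxd13, 1.19% at Hoxd1). The strongest peaks counted for Hoxa4 and Hoxb2 lie inside Hoxa3 and Hoxb3. The 0% of Hoxa3 was measured around its outermost annotated TSS, at 52213336 on chromosome 6. It does not describe the rest of that gene, which holds the peak counted for Hoxa4 (52172179 to 52172565). In the pooled list the clusters held 6 (HoxA), 12 (HoxB), 4 (HoxC) and 7 (HoxD) peaks. In replicate 1 alone they held 23 (HoxA), 26 (HoxB), 12 (HoxC) and 11 (HoxD) peaks, with 9.30% at Hoxa4 and 11.2% at Hoxb2. In replicate 2 alone they held 3 (HoxA), 3 (HoxB), 0 (HoxC) and 1 (HoxD), with 1.52% at Hoxa4 and 1.40% at Hoxb2.

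Some gene families, picked after their values were seen, had few or no peaks. Of 331 vomeronasal receptor genes (Vmn) 2 had a replicated peak within 20 kb, and of 1135 olfactory receptor genes (Olfr) 13. The cornified-envelope genes Sprr (15 genes), the glucuronosyltransferases Ugt (22) and the epidermal Skint genes (11) had 0. A median of 0% can hardly fall below matched random lists, whose medians here were 0% to 0.0700%, so the permutation test says nothing about these 5 families. Among 253 families of at least 10 genes the lowest permutation p belonged to transmembrane protein genes (Tmem, median 0.752% over 242 genes, 147 of them with a peak), followed by annexins (Anxa, 2.4999% over 11 genes), which bind membranes in the presence of calcium, protein phosphatase genes (Ppp, 1.02% over 75 genes) and AT-rich interaction domain genes (Arid, 2.81% over 10 genes). By the permutation test against 10000 matched random lists 42 families had an unadjusted p under 0.05 and 0 passed after adjustment (Tmem and Anxa 0.0506, Ppp and Arid 0.0632). The smallest permutation p that 10000 lists can give is 0.00020, that of Tmem. If only 1 family reaches it, adjustment over 253 families turns it into 0.0506. A single family could therefore not pass, and the lack of a pass does not show that no family stands out.

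Chromosome X held 5 of the 26527 replicated peaks and 316 of the 102131 peaks of replicate 1, and with 1 group in the design no biological explanation was tested between groups. A low gene number is argued against, since X had 242 times fewer replicated peaks per protein-coding gene. Fewer X copies in pools of both sexes (0.75 of the autosomal depth if the sexes are equal in number) would leave 84.2% of autosomal peaks of replicate 1, which is 12.4 times the observed X share per gene, and the expected number stayed at least 5.87 times the observed one at each read minimum tried in replicate 1. Marking of 1 active X only (0.5 of the depth) gave 4.79 times the observed share at the nominal minimum of 7 reads, and 48.1 times in replicate 2, 13.9 in the pooled list and 38.7 in the replicated list at theirs, a bound that decides little because calls near that minimum are incomplete (41 peaks of replicate 1 at 7 reads, 21723 at 10). From the most frequent read number of each list on, 171 X peaks were expected at 0.5 of the depth and 230 observed in replicate 1 (from 10 reads, a ratio of 0.746), 3.59 and 1 in replicate 2 (from 14), 7.21 and 8 in the pooled list (from 22) and 2.05 and 2 in the replicated list (from 24). In replicate 1 the ratio of expected to observed fell further at higher minimums, to 0.511 at 11 reads (69.5 expected, 136 observed), 0.471 at 12 (26.8 and 57) and 0.425 at 15 (1.70 and 4), so more X peaks were seen there than halved autosomal peaks give. The pooled and replicated lists thus lay near the expected number, but on only 8 and 2 observed peaks. All replicated peaks are pooled peaks, so these 2 lists are not independent. The lower value of replicate 2 rests on 1 observed peak. Replicate 1 held more X peaks than expected. Marking of a single X is neither shown nor ruled out, and it stays open together with any filter applied by the authors, which was not tested.

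Replicate 2 had 12767 peaks and replicate 1 had 102131, and with 1 group no biological explanation was tested. A shallower ChIP library is argued against by the recovered background, which before scaling was 1.00 times that of replicate 1. A shallower control is in line with the reads at summits: 9024 peaks of replicate 1 and 6412 of replicate 2 had at least 15 reads, a ratio of 1.41, and at 20 reads the numbers were 366 and 381, and at 25 reads 28 and 16. The ratio was 6.65 at 10 reads and 3.35 at 12, below the most frequent read number of replicate 2 (14), where its calls are incomplete. Replicate 2 was called against 1 control file, its ChIP reads were scaled by 0.549, and its weakest peak had 10 reads at the summit where that of replicate 1 had 7. Taking the depth that ChIP reads were scaled to as that of the control, the control of replicate 2 was 0.469 times as deep as that of the pooled list, which used both files. The control may thus account for missing weak peaks, while the replicate 2 peaks not shared with replicate 1 were not addressed by this test.

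Stomach genes were not covered more than genes of other organs in the replicated list (0.810% against 0.948%). If the strongest peaks lay at genes used in many organs, the strongest 26527 peaks of replicate 1 should favour stomach genes no more than others, and their ratio of stomach to other-organ coverage was 1.23 (permutation p = 0.358), which neither meets nor excludes this. The ratio was 1.04 in the next 26527 peaks (permutation p = 0.841) and 1.48 in the 49077 weakest (1.53% against 1.03%, permutation p = 0.0037), so it followed no steady order of strength, and the classes were not tested against each other. Less specific peaks of replicate 2 are another candidate explanation, with a ratio of 0.772 there (permutation p = 0.428), so both explanations stay open. With 1 group in the design no biological explanation was tested.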
